A study of Mus musculus with 64 samples.

How the data were processed

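Gene expression was measured in the livers of male and female C57BL/6J mice with one-colour Agilent microarrays, each hybridised with Cy3-labelled cRNA made from total RNA. The data were 64 arrays in 8 groups of 8, formed by sex, by diet (CD, the chow diet, or WD, the Western diet) and by amino acid source. The label AA marks diets whose protein had been replaced by a mixture of free amino acids, and the label CAS was read as the diets that kept their protein. Groups and replicate numbers were taken from the sample titles. The labels also name 2 wash batches, each of which held 4 arrays of every group, and an unnamed number from 1 to 64 whose meaning is not given in the sources used here. Each array was treated as 1 animal. The labels do not say so outright, so that p-values measure the spread between these arrays.

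The deposited values were log2 intensities, 1 per probe and array, in 1 table of 35356 rows. Agilent Feature Extraction 10.10.1.1 and limma were used by the authors, per the submitters' processing notes, which give no version of limma and no order of steps. The method of background correction, any filter on probes and the averaging of repeated spots are not given in the sources used here. The scale and the normalization were read from the values. The highest value was 18.64 on every array and the array medians lay between 6.729 and 6.740, as quantile normalization between arrays gives. Probes had not been centred, since their means spanned the range of a scanner. Such normalization removes any difference in total signal between arrays, so that a change of most transcripts in 1 direction would not be seen. Arrays carry no read depth, and the number of arrays limits the precision. The 95% confidence interval of a log2 difference reached 0.196 to either side for the median probe for 2 groups of 8 and 0.277 for a difference of differences.

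No table that pairs the probe identifiers with genes was among the files used here, so that all results are given by probe and no gene is named. Several probes can measure the same gene, and a number of probes is not a number of genes. The planned choice of 1 probe per gene, the mean of all probes of a gene, the tests of preset gene lists and the check of sex labels on sex-linked genes could not be run for this reason. Of the table's rows, 115 were control features (10 E1A, 91 ERCC, 12 ETG and 2 background controls) and were left out of the tests. Of the 35241 remaining probes, 3 had fewer than 4 values in some group and were left out, which left 35238 probes. Missing values numbered 400 in 194 rows and were not filled in. The DarkCorner and 3xSLv1 background controls had means of 4.18 and 4.09. Of the tested probes, 6333 (18.0%) had a mean below 5, close to that background, where differences are compressed. The E1A controls had SDs between 0.0846 and 0.162 across the 64 arrays, over means from 4.24 to 17.60.

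Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) and the table was read with data.table (version 1.17.8). A single model with 8 group means and the wash batch was fitted to all 64 arrays, which had 55 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe was called at an adjusted p under 0.05. There were 15 comparisons: AA against CAS in each sex and diet, WD against CD in each sex and amino acid source, the interaction of diet and amino acid source in each sex, the sex differences of these effects, and females against males. Every difference is the first named group minus the second, and each sex difference is the female effect minus the male effect. The groups, the model, the threshold and the alternatives listed first below were fixed before the data were examined. The naming of probes departed from the rule fixed at the same time. That rule named more probes, up to 8 in each direction for AA against CAS and WD against CD. It took interaction probes by the smallest p whatever their direction, and it did not mention the sex differences of effects. For AA against CAS, WD against CD and females against males, they were the 2 called probes with the largest positive and the 2 with the largest negative difference among probes at or above the median level of 6.74. For an interaction or sex difference, they were the called probes with the smallest p under the same filter, 2 in each direction. The part of the fixed rule on clone and predicted gene names could not be applied. Effects were compared between sexes, diets or sources only between comparisons that share no array, by the correlation across probes with a jackknife standard error over arrays, and by the overlap of called probes against the number that independent lists would share.

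The alternatives fixed beforehand were each wash batch alone, no wash batch term, the replicate number as a block, runs of 8 consecutive unnamed numbers as a block, the probes at or above the median mean level alone, a second quantile normalization, estimated array weights, eBayes with trend and robust options, and fits of the compared groups alone. Leaving out each array in turn, and leaving out the 4 arrays with the lowest correlations within their group, were added after seeing the data. The model was tested on simulated data with 200 changed probes among 35238. For AA against CAS in females on WD, it recovered 5.97%, 74.6% and 97.0% of probes changed by 0.25, 0.5 and 1 on the log2 scale. The recovered shares were 1.49%, 37.3% and 90.9% for the female interaction, and 4.48%, 43.3% and 95.5% for the sex difference of the AA effect on CD.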

Results

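Liver RNA of C57BL/6J mice was profiled on 64 arrays, 8 in each combination of sex, diet and amino acid source. The mice had been bought at 6 weeks of age and kept for 1 week before the diets began. Both diets were fed for 15 weeks, with 12 mice in each group. The chow diet (CD) held 70% carbohydrate and 4% fat, the Western diet (WD) held 61% carbohydrate and 20% fat, and both held 14% protein or the matching amino acid mixture. The AA diets replaced the protein (CAS) by free amino acids in the proportions of casein, the main milk protein. The comparisons ask how the liver responded to a Western diet, and whether the source of amino acids changed that response in each sex. Median correlations of an array with the others of its group lay between 0.986 and 0.995. The median residual SD of a probe was 0.197 on the log2 scale.

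Sex was the main difference between the livers. The first principal component took 30% of the variance and separated all males from all females, with group means between -41.73 and -21.61 in males and between 28.97 and 32.51 in females. The second component took 12.45% and followed the diet. Among males it averaged 22.74 ± 7.71 in CAS-fed mice on CD and -39.25 ± 10.64 in CAS-fed mice on WD (SD, n = 8 each). The AA-fed males lay between them, at 9.36 ± 12.9 on CD and -6.73 ± 8.00 on WD. Females on CD averaged 19.44 ± 6.26 with CAS and 13.68 ± 5.36 with AA, and females on WD averaged -9.91 ± 4.64 with CAS and -9.33 ± 3.29 with AA.

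**Figure D1:**
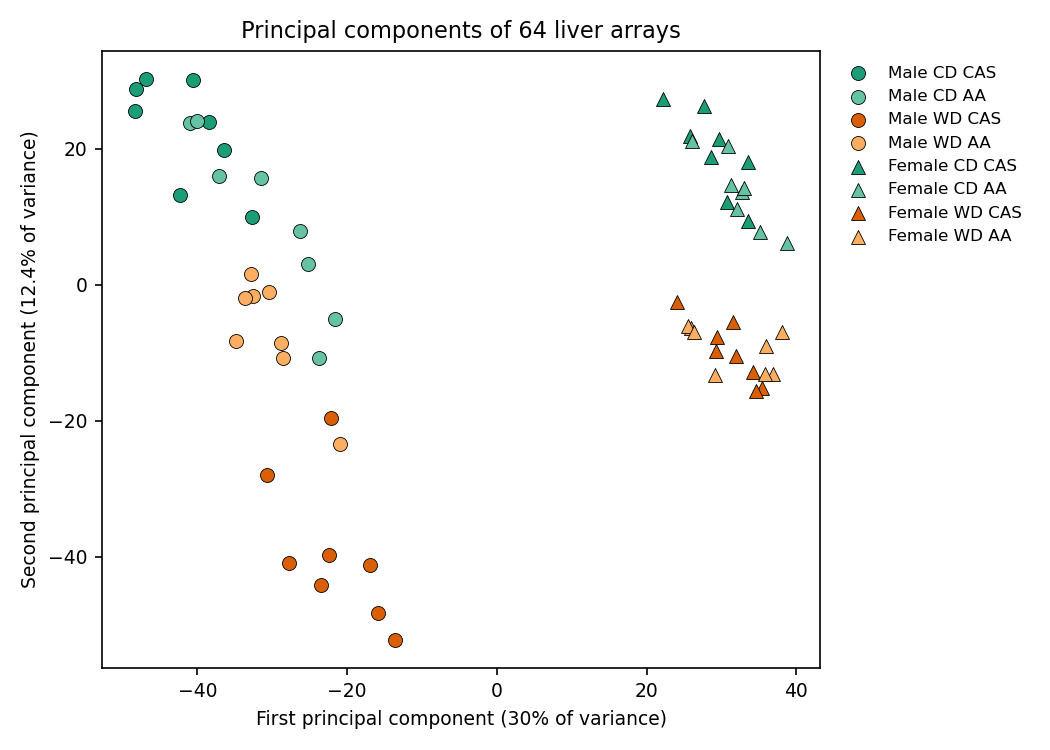
Each point is 1 liver array, placed by its scores on the first principal component (x axis, 30% of the variance) and the second (y axis), with circles for males, triangles for females and colours for diet and amino acid source. CAS-fed males on WD averaged -39.25 on the second component and AA-fed males on WD averaged -6.73.

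Between the sexes, 14567 probes differed, 7034 higher in females and 7533 higher in males. Of these, 210 were higher in females and 208 higher in males by at least 1 on the log2 scale. The probe A_55_P1952512 was 9.73 ± 0.13 (SE) higher in females (adjusted p = 5.3e-58), and A_55_P1952517 was 9.06 ± 0.15 higher (adjusted p = 1.5e-51). The probes A_55_P2152607 and A_55_P2043083 were higher in males, with differences of -8.18 ± 0.08 (adjusted p = 4.0e-64) and -7.90 ± 0.08 (adjusted p = 7.4e-66). In CAS-fed mice on CD, A_55_P1952512 had a level of 14.20 ± 0.46 in females and 4.24 ± 0.09 in males, and A_55_P2043083 had 4.56 ± 0.13 in females and 12.23 ± 0.27 in males (SD, n = 8). The lower of each pair of levels lay near the background controls, so that these differences are lower limits. Within wash batches 1 and 2, 7637 and 10796 probes were called, and 98.8% and 97.7% of them had the same sign in the other batch. Among probes at or above the median level alone, 9392 probes were called.

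Of the 4 diet comparisons, that of CAS-fed males called the most probes, 10291 in all, 4962 higher and 5329 lower. By at least 1 on the log2 scale, 463 probes rose and 257 fell. The probe A_51_P490456 rose from 7.19 ± 0.77 on CD to 13.84 ± 0.53 on WD (SD, n = 8), a difference of 6.65 ± 0.41 (SE) or 100.3-fold (adjusted p = 9.3e-20). The probe A_51_P156955 rose from 5.72 ± 0.65 to 12.12 ± 0.90, by 6.40 ± 0.68 or 84.3-fold (adjusted p = 5.0e-11). The probes A_55_P2153517 and A_51_P497090 fell by 4.34 ± 0.35 and 4.26 ± 0.35 on the log2 scale, from 12.69 ± 0.44 to 8.35 ± 0.16 and from 12.05 ± 0.45 to 7.79 ± 0.18 (adjusted p = 1.5e-15 and 3.2e-15). The fits within wash batches 1 and 2 called 4051 and 6181 probes, of which 98.1% and 95.7% had the same sign in the other batch. The majority turned in batch 1, with 2363 higher and 1688 lower.

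In AA-fed males the Western diet changed 831 probes, 497 higher and 334 lower, of which 100 rose and 13 fell by at least 1. The probe A_66_P122294 rose from 6.38 ± 1.68 on CD to 10.54 ± 0.87 on WD (SD, n = 8), by 4.16 ± 0.59 (SE) or 17.9-fold (adjusted p = 2.8e-06). The probe A_55_P2122841 rose from 10.00 ± 1.59 to 13.30 ± 0.94, by 3.30 ± 0.47 (adjusted p = 2.8e-06). The probes A_52_P16752 and A_55_P2928440 fell by 1.39 ± 0.16 and 1.31 ± 0.34 (adjusted p = 1.7e-08 and 0.018), the latter by only 0.52 in wash batch 1 alone (adjusted p = 0.699). The probes named for increases in CAS-fed males moved less: A_51_P490456 rose by 2.43 ± 0.41 (adjusted p = 1.0e-04), and A_51_P156955 differed by 0.27 ± 0.68 (adjusted p = 0.92). Their interactions of diet and source were -4.21 ± 0.58 and -6.13 ± 0.97 (adjusted p = 8.3e-07 and 1.1e-05). A_51_P490456 and A_51_P156955 were picked for their rise in CAS-fed males, so that a smaller rise elsewhere may partly follow from that choice. The probes named for increases in AA-fed males likewise moved less in CAS-fed males. There A_66_P122294 went from 7.26 ± 1.39 to 10.38 ± 0.32 and A_55_P2122841 from 11.57 ± 1.20 to 11.73 ± 0.34 (SD, n = 8). Within wash batches 1 and 2, 180 and 212 probes were called, of which 87.2% and 86.8% had the same sign in the other batch. A fit of these groups alone called 474, and 540 were called without Male WD AA replicate 6.

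In CAS-fed females the Western diet changed 2208 probes, 1213 higher and 995 lower, with 113 higher and 45 lower by at least 1. The probe A_51_P343517 rose from 8.18 ± 0.54 on CD to 11.91 ± 0.83 on WD (SD, n = 8), by 3.73 ± 0.41 (SE) or 13.3-fold (adjusted p = 1.9e-09). The probe A_55_P2070869 rose by 3.14 ± 0.68 (adjusted p = 0.0020), with levels of 9.69 ± 0.75 and 12.83 ± 2.02, but by 4.43 and 1.85 in wash batches 1 and 2 alone, where it was not called (adjusted p = 0.0612 and 0.160). The probes A_55_P2622908 and A_51_P497090 fell by 2.12 ± 0.39 and 2.08 ± 0.35 on the log2 scale (adjusted p = 2.4e-04 and 4.4e-05). With 4 arrays per group, wash batches 1 and 2 alone called 109 and 1017 probes, and 98.2% and 94.6% of these had the same sign in the other batch. Estimated array weights gave 3378.

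In AA-fed females the diet changed 711 probes, 391 higher and 320 lower, with 76 higher and 24 lower by at least 1. The probe A_51_P343517 rose here too, from 8.49 ± 0.72 to 11.36 ± 1.14 (SD, n = 8), by 2.87 ± 0.41 (SE) or 7.33-fold (adjusted p = 4.2e-06). The probe A_52_P205255 rose from 6.40 ± 0.42 to 9.06 ± 0.61, by 2.66 ± 0.24 (adjusted p = 1.2e-11). The probes A_55_P2153517 and A_51_P497090, which were also named for decreases in CAS-fed males, fell by 2.45 ± 0.35 and 2.43 ± 0.35 (adjusted p = 3.3e-06 and 3.6e-06). In wash batches 1 and 2 alone, 35 and 396 probes were called, of which 100% and 93.7% had the same sign in the other batch.

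**Figure D2:**
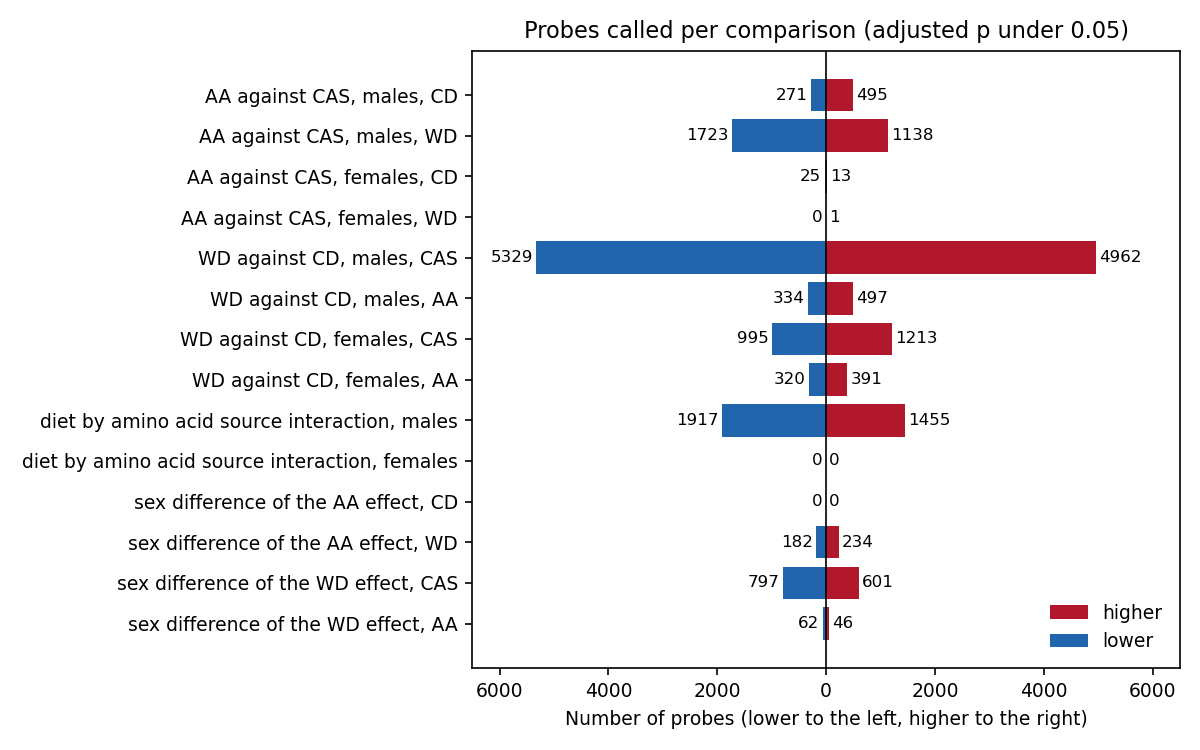
Bars give the number of probes called at an adjusted p under 0.05 in each comparison except females against males, with higher probes to the right of 0 and lower probes to the left. CAS-fed males had 4962 higher and 5329 lower probes on WD, and AA-fed males had 497 and 334.

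The responses to the Western diet were positively correlated between sexes and between sources. Across probes, the differences of CAS-fed males and CAS-fed females correlated with r = 0.593 ± 0.064 (jackknife SE over arrays). Of the probes called in both, 849 rose in both sexes and 691 fell in both, and 29 moved in opposite directions, where independent lists would give 170.8, 150.5 and 323.6. In AA-fed mice the correlation between the sexes was 0.364 ± 0.110, with 99 probes higher in both, 32 lower in both and 6 opposite (5.5, 3.0 and 8.2 if independent). Between CAS-fed and AA-fed females it was 0.651 ± 0.073, with 275 higher in both, 202 lower in both and 0 opposite (13.5, 9.0 and 22.1 if independent). Between CAS-fed and AA-fed males it was 0.373 ± 0.171, with 330 higher in both, 161 lower in both and 32 opposite (70.0, 50.5 and 122.2 if independent). Probes are not independent replicates, so that no p is given for these correlations.

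Free amino acids in place of protein changed 2861 probes in males on WD, 1138 higher and 1723 lower, with 65 higher and 121 lower by at least 1. The probe A_55_P2111980 rose from 9.56 ± 2.02 in CAS-fed to 12.65 ± 1.28 in AA-fed males (SD, n = 8), by 3.08 ± 0.50 (SE) or 8.48-fold (adjusted p = 1.8e-05). The probe A_51_P456208 rose by 2.68 ± 0.44 (adjusted p = 2.6e-05). The probe A_51_P490456, named above for its increase on WD, fell by 3.71 ± 0.41 from 13.84 ± 0.53 to 10.13 ± 1.36 (adjusted p = 1.8e-09). The probe A_51_P467076 fell by 3.55 ± 0.57 from 8.75 ± 2.36 to 5.20 ± 1.20 (adjusted p = 1.8e-05). The lower level lay above the background controls (4.18 and 4.09) but spread widely, so that the difference may be compressed. Wash batches 1 and 2 alone called 296 and 1275 probes, of which 97.6% and 94.2% had the same sign in the other batch, and the differences of the 2 batches correlated across probes with r = 0.566.

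In males on CD, AA feeding changed 766 probes, 495 higher and 271 lower, with 36 higher and 30 lower by at least 1. The probe A_51_P156955, which WD had raised in CAS-fed males, rose from 5.72 ± 0.65 to 8.66 ± 1.17 (SD, n = 8), by 2.94 ± 0.68 (SE) or 7.66-fold (adjusted p = 0.013). The probe A_51_P180492 rose by 2.36 ± 0.68 (adjusted p = 0.047). The probes A_51_P339098 and A_51_P509679 fell by 2.23 ± 0.45 and 1.80 ± 0.39 (adjusted p = 0.0033 and 0.0074). Fitted on these groups alone, 225 probes were called and the last 3 probes had adjusted p = 0.0736, 0.0626 and 0.0630, array weights gave 1477 probes, and wash batches 1 and 2 alone gave 0 and 139. The number rested on single arrays: it was 202, 1426, 345 and 342 without Male CD AA replicates 3, 4, 6 and 7, and 1292, 250 and 230 without Male CD CAS replicates 5, 7 and 8. It was also 1225 without the 4 arrays of lowest correlation, none of which belongs to these groups.

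In females on CD, AA feeding changed 38 probes, 13 higher and 25 lower, of which 11 fell and 0 rose by at least 1. The probes A_52_P595871 and A_55_P2058861 rose by 0.95 ± 0.21 and 0.87 ± 0.19 (SE, adjusted p = 0.033 for both), from 9.74 ± 0.28 to 10.69 ± 0.49 and from 11.13 ± 0.40 to 12.00 ± 0.33 (SD, n = 8). The probe A_30_P01019037 fell by 1.95 ± 0.45 (adjusted p = 0.047) and A_55_P2099594 fell by 1.69 ± 0.37 (adjusted p = 0.036). None of these 4 probes passed when the compared groups were fitted alone, which called 1 probe (adjusted p = 0.101, 0.116, 0.285 and 0.270 in that order), and wash batches 1 and 2 alone called 0 and 16. The number changed with single arrays: it was 5, 68, 17, 24, 1 and 4 without Female CD CAS replicates 1, 2, 3, 6, 7 and 8, and 75, 0, 9, 11 and 13 without Female CD AA replicates 3, 5, 6, 7 and 8. Without the 4 arrays of lowest correlation, which include Female CD AA replicate 5, it was 9 (5 higher, 4 lower), and array weights gave 27 higher and 18 lower.

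In females on WD, AA feeding changed 1 probe, and 677 probes had an unadjusted p under 0.05. That probe, A_51_P279693, lies below the level set for naming probes and was picked out after its values were seen. Its level was 4.48 ± 0.25 in CAS-fed and 5.18 ± 0.21 in AA-fed females (SD, n = 8), a difference of 0.69 ± 0.12 (SE, adjusted p = 0.020 in limma). Both levels are close to the background controls. No probe was called in wash batch 1 or 2 alone, in the compared groups alone (0), or without any 1 of Female WD CAS replicates 1, 4, 5 and 8 and Female WD AA replicates 5, 6 and 8 (0 each), and 2 were called without Female WD AA replicate 2, with array weights, or without the 4 arrays of lowest correlation.

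The AA effects on the 2 diets ran against each other in males. Across probes their correlation was -0.345 ± 0.146 (jackknife SE), and 166 probes called on both diets moved in opposite directions, where independent lists would give 33.0. On both diets, 5 probes rose and 4 fell, where independent lists would give 16.0 and 13.2. In females the correlation was 0.078 ± 0.147. Between the sexes, the AA effects correlated with r = 0.388 ± 0.135 on CD and 0.114 ± 0.105 on WD. The AA effect of females on WD correlated with r = -0.171 between wash batches 1 and 2. Correlations with it may therefore be low from noise alone.

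The interaction of diet and amino acid source was called for 3372 probes in males, 1455 positive and 1917 negative. A positive value means that the AA effect was higher on WD than on CD. The probe A_55_P1989673 had an interaction of 1.97 ± 0.18 (SE, adjusted p = 4.0e-12): WD lowered it from 11.70 ± 0.23 to 9.48 ± 0.24 in CAS-fed males (SD, n = 8), and its levels in AA-fed males were 11.26 ± 0.38 on CD and 11.02 ± 0.36 on WD. The probe A_52_P150236 had 1.07 ± 0.12 (adjusted p = 4.2e-09). The probe A_52_P64376 had -3.18 ± 0.34 (adjusted p = 1.1e-09), with levels of 5.74 ± 0.30 and 8.99 ± 0.30 in CAS-fed and of 6.57 ± 0.58 and 6.64 ± 0.90 in AA-fed males on CD and WD. The probe A_55_P2110713 had -2.30 ± 0.25 (adjusted p = 1.4e-09). The separate fits of wash batches 1 and 2 called 617 and 1099 probes, of which 94.2% and 93.6% had the same sign in the other batch. In females limma called 0 probes for this interaction, with 1516 at an unadjusted p under 0.05 and a smallest adjusted p of 0.506.

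**Figure D3:**
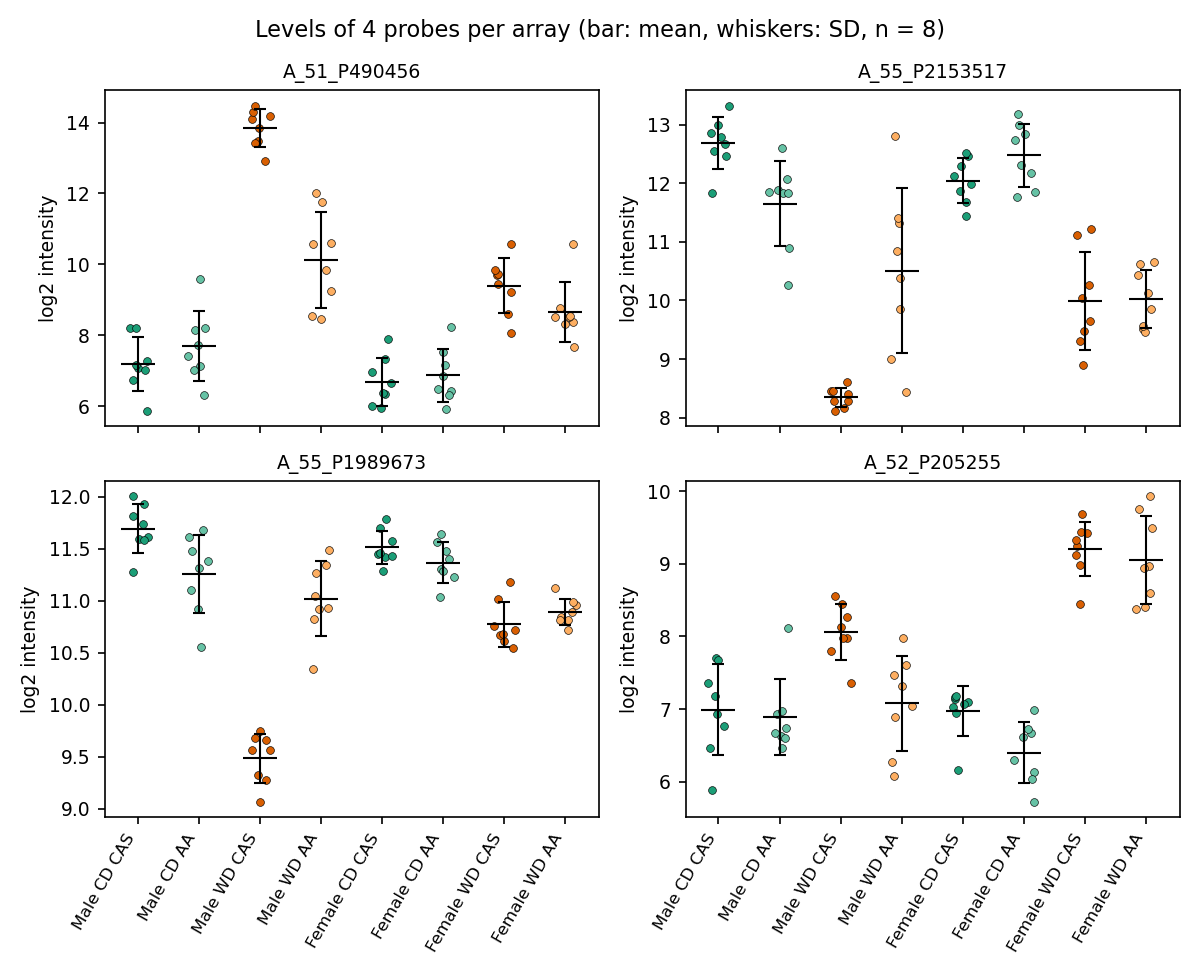
Points are log2 intensities of 4 probes on single arrays of the 8 groups (y axis), with a bar at the mean and whiskers of 1 SD (n = 8). The level of A_51_P490456 averaged 13.84 in CAS-fed and 10.13 in AA-fed males on WD.

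The sex difference of the AA effect was called for 416 probes on WD, 234 positive and 182 negative, and for 0 probes on CD. On WD, A_55_P2110713 had a difference between the sexes of 1.96 ± 0.25 (SE, adjusted p = 3.9e-07). Its level was 12.73 ± 0.57 in CAS-fed and 10.69 ± 0.60 in AA-fed males on WD, and 11.21 ± 0.23 and 11.12 ± 0.38 in females (SD, n = 8). The probe A_51_P165342 had 1.64 ± 0.22 (adjusted p = 2.9e-06), A_55_P1989673 had -1.42 ± 0.18 (adjusted p = 3.8e-07), and A_51_P121915 had -1.42 ± 0.19 (adjusted p = 3.2e-06). On CD, limma gave 2035 probes at an unadjusted p under 0.05 and a smallest adjusted p of 0.329, so that the 766 probes of males and the 38 of females are not shown to differ. On WD, wash batches 1 and 2 alone called 11 and 127 probes, array weights gave 850, and 642 were called without Male WD AA replicate 3. The majority turned to 61 positive and 66 negative in wash batch 2, and to 179 and 188 among probes at or above the median level.

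The sex difference of the WD effect was called for 1398 probes in CAS-fed mice, 601 positive and 797 negative. The probe A_51_P327451 had 1.66 ± 0.18 (SE, adjusted p = 4.4e-09): it moved from 12.06 ± 0.26 to 11.24 ± 0.41 in males and from 8.98 ± 0.24 to 9.83 ± 0.29 in females (SD, n = 8). The probe A_55_P2740937 had 2.36 ± 0.28 (adjusted p = 3.0e-08), A_55_P1991416 had -1.86 ± 0.22 (adjusted p = 3.6e-08), and A_52_P570240 had -1.88 ± 0.24 (adjusted p = 1.4e-07). The last of these rose from 6.37 ± 0.23 to 8.17 ± 0.58 in males and had levels of 6.80 ± 0.10 and 6.73 ± 0.27 in females. In separate fits of wash batches 1 and 2, 143 and 359 probes were called.

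In AA-fed mice the sex difference of the WD effect was called for 108 probes, 46 positive and 62 negative. The probe A_52_P205255 had 2.46 ± 0.34 (SE, adjusted p = 2.5e-05), with levels on CD and WD of 6.89 ± 0.52 and 7.08 ± 0.65 in males and of 6.40 ± 0.42 and 9.06 ± 0.61 in females (SD, n = 8). The probe A_52_P659312 had 1.504 ± 0.27 (adjusted p = 0.0013), A_51_P485791 had -2.15 ± 0.30 (adjusted p = 2.5e-05), and A_66_P104901 had -2.62 ± 0.39 (adjusted p = 5.0e-05). Wash batches 1 and 2 alone called 1 and 13 probes, and the groups fitted alone called 56. None of these named probes was called in batch 1, where A_52_P659312 had 0.98 (adjusted p = 0.898). A_52_P205255 was called in neither batch (adjusted p = 0.0763 and 0.109). With runs of 8 unnamed numbers as a block, 80 were positive and 71 negative.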

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

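The tests of shared arrays, of deviating arrays, of the spread within each sex and of the sex difference behind the amino acid effect on WD, and the splits without 1 array, were chosen only after those results were seen. For the counts of probes, 100 splits of the same arrays into groups of the same sizes were drawn, the real one included, on the 35047 probes without a missing value. For interactions and sex differences, the additive effects were removed first. A share of 1 of 100 is the smallest these splits can give, and the shares are not adjusted over the 15 counts.

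A first pattern was that AA feeding moved the livers of males on WD back along the Western diet response. The probes that respond to WD in CAS-fed males were chosen in 1 wash batch and scored in the other, so that no array served in both steps. The score of AA-fed minus CAS-fed males on WD was -0.307 and -0.3046 in the held-out batches, with 4 of 4 AA-fed mice below all CAS-fed mice each time (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 allows, and adjusted p = 0.114 over 8 such tests), which argues against arrays shared by the comparisons. With 1 AA-fed and 1 CAS-fed array of the held-out batch left out together, in each of 16 pairs per batch, the score stayed between -0.381 and -0.2415. Its sign could not turn, since all AA-fed mice lay below all CAS-fed mice, so that the sign is no further evidence. Its size stayed above the SD of the CAS-fed arrays (0.0284 in wash batch 1 and 0.135 in wash batch 2), and so did not rest on 1 array of either group. A biological effect of the amino acid source in males on WD may remain as a hypothesis, and lower intake of the AA diet or body weight stays open, since neither was analysed here.

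A further pattern was that AA feeding called 2861 probes in males on WD and 1 in females on WD. A larger spread between females than between males might hide effects in females, but the within-group SD of the median probe was 1.027 times that of males. The sex difference itself was called for 416 probes, and 1 of 100 splits, the real one, gave as many (440 probes after removal of the additive effects, highest other 317), but without Male WD AA replicate 7, whose removal gave the lowest count, 2 of 100 did and the highest other (781) exceeded the real 299. That is consistent with a difference between the sexes, whose size depended on single arrays (282 to 642 probes without 1) and whose cause was not tested. In simulated data with noise independent between probes, 74.6% of probes changed by 0.5 in females on WD were recovered. Of those changed by 0.25, 5.97% were recovered. The median called difference of males on WD was 0.416 in size, so that effects of the male size could have been missed in part of the probes. How large a part is not known from this simulation, which changed only 200 probes. The adjusted threshold is less strict when as many probes change as in males, so that the recovered shares may be too low for such a response.

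For the male interaction of diet and source (3372 probes), 1 of 100 splits, the real one with 3361, gave as many, and the highest other gave 472. The values were 1 of 100 for the sex difference of the WD effect in CAS-fed mice (1398 probes, highest other 6) and 1 of 100 in AA-fed mice (108 probes, highest other 1). For each count on its own, no other split gave as many for WD against CD in CAS-fed males (1 of 100, real 10264, highest other 4584), AA-fed males (1 of 100, 825 against 109), CAS-fed females (1 of 100, 2200 against 395) and AA-fed females (1 of 100, 707 against 187). The same held for females against males (1 of 100, 14506 against 370), and for AA against CAS in males on CD (1 of 100, 764 against 555) and males on WD (1 of 100, 2844 against 2281). Without the array whose removal gave the lowest count, the splits of the remaining arrays gave 1 of 100 in both (205 against 157 on CD, 2152 against 2121 on WD). For AA in females on CD, 3 of 100 splits gave at least the real 38 probes and the highest other gave 65, so that chance is not clearly excluded. It was not excluded for females on WD (11 of 100 splits gave at least 1 probe, highest other 69). The female interaction and the sex difference of the AA effect on CD called 0 probes, so that splits cannot test them (highest other 12 and 43). A split that called 69 probes against a real value of 1 may point to a structure among the female arrays on WD besides the groups, which was not tested, and the median over the splits was 0.

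Single probes differed between conditions by a test of the difference itself. In the male interaction, A_55_P1989673 had 1.97, A_52_P150236 had 1.07, A_52_P64376 had -3.18 and A_55_P2110713 had -2.30 on the log2 scale. In the sex difference of the AA effect on WD, A_55_P2110713 had 1.96, A_51_P165342 had 1.64, A_55_P1989673 had -1.42 and A_51_P121915 had -1.42. In the sex difference of the WD effect, the CAS-fed values were 1.66 for A_51_P327451, 2.36 for A_55_P2740937, -1.86 for A_55_P1991416 and -1.88 for A_52_P570240. The AA-fed values were 2.46 for A_52_P205255, 1.504 for A_52_P659312, -2.15 for A_51_P485791 and -2.62 for A_66_P104901.

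Among 184 groups of 8 arrays examined for a sample far from the rest, 12 had one, and chance alone gives about 1 in 20. Female WD AA replicate 2 had a median correlation with its group of 0.9866 (others 0.9924 to 0.9949) and Male WD AA replicate 6 had 0.9857 (others 0.9918 to 0.9938). Male WD AA replicate 3 lay at -20.96 on the first principal component, with the others between -34.82 and -28.52. The mean level of female-biased probes was 9.36 in Female WD CAS replicate 4 (others 9.64 to 9.79), and that of male-biased probes was 8.05 in Female WD AA replicate 4 (others 7.70 to 7.84). The probe A_52_P64376 had 7.81 in Male CD AA replicate 3 (others 6.03 to 6.86), A_51_P165342 had 9.32 in Male WD CAS replicate 5 (others 8.39 to 8.74), and A_51_P327451 had 12.62 in Male CD CAS replicate 1 (others 11.76 to 12.15). In Male CD AA replicate 4, A_52_P205255 had 8.12 (others 6.46 to 6.97) and A_66_P104901 had 8.42 (others 10.50 to 11.65). The probe A_55_P2152607, higher in males, had 5.03 in Female CD AA replicate 5 (others 4.25 to 4.61) and 4.91 in Female CD CAS replicate 2 (others 4.25 to 4.55). On the former array the DarkCorner background control read 5.75, against a mean of 4.18 over all arrays.

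The control probe ERCC-00170_100, which is not part of any comparison, averaged 5.68 ± 0.35 (SD) over the 64 arrays, 1.495 above the DarkCorner control.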

How the results depend on the processing

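Leaving out each array in turn and leaving out the 4 arrays of lowest correlation were chosen only after the results were seen, as were all settings of the scores. The cause of the changes below was not tested, except that a single wash batch holds 32 of the 64 arrays. No named probe and no score changed sign past its spread under the settings run for it. All 15 counts stayed within 1.5 times under no wash batch term, a second quantile normalization, eBayes with trend and robust, and blocks of runs of 8 unnamed numbers. Replicate numbers were not taken as pairs: the deviations of same-numbered arrays correlated by 0.0125 on average (-0.381 to 0.439 over 224 pairs), and 14 of 64 arrays lay closest to their own number, against a mean of 8.03 and at least 14 in 49 of 1000 reassignments of the numbers, a test added after seeing the data. With the replicate block in place of the wash batch, counts stayed within 1.5 times, for example 714 for AA in males on CD and 2743 on WD. Wash batches 1 and 2 alone gave 0 and 139 probes for AA in males on CD, 296 and 1275 in males on WD, 0 and 16 in females on CD and 0 and 0 in females on WD. For WD they gave 4051 and 6181 in CAS-fed males, 180 and 212 in AA-fed males, 109 and 1017 in CAS-fed females and 35 and 396 in AA-fed females. For the male interaction they gave 617 and 1099, for the sex difference of AA on WD 11 and 127, for that of WD 143 and 359 (CAS) and 1 and 13 (AA), and batch 1 gave 7637 for sex. Array weights gave 1477 for AA in males on CD, 2 in females on WD, 3378 for WD in CAS-fed females and 850 for the sex difference of AA on WD. The compared groups alone gave 225, 1 and 0 for AA in males on CD, females on CD and females on WD, 474 for WD in AA-fed males and 56 for the sex difference of WD in AA-fed mice. Without the 4 arrays the AA counts were 1225 in males on CD, 9 in females on CD and 2 in females on WD. Among probes at or above the median level alone, 0 were called for AA in females on WD and 9392 for sex. Leaving out 1 array gave 202 to 1426 for AA in males on CD, 2164 to 3214 in males on WD, 0 to 75 in females on CD and 0 to 2 in females on WD. It gave 9244 to 10485 and 540 to 1050 for WD in CAS-fed and AA-fed males, 1649 to 2247 and 489 to 784 in females, 2520 to 3866 for the male interaction, 282 to 642 for the sex difference of AA on WD, and 1110 to 1653 and 76 to 153 for that of WD. Both counts of 0 stayed at 0 under every setting run. Of the 48 named probe results, 23 and 8 lost their call in wash batch 1 and 2 alone, 7 with the compared groups alone, 3 with trend and robust, 3 without the 4 arrays and 2 with array weights, and none did under the other settings run for them. Leaving out 1 array was run for the counts only. Where it took the count for AA in females on CD to 0, the probes named there lost their call too. The share of higher calls moved by over 10 points in several comparisons. For AA in females on CD it went from 34.2% to 60.0% with array weights, 55.6% without the 4 arrays, 50.0% in batch 2 and 0% in the compared groups alone. For AA in males it went from 64.6% to 51.8% (batch 2) and 75.6% (compared groups) on CD and from 39.8% to 22.6% (batch 1) on WD. For WD, batch 1 moved it from 48.2% to 58.3% in CAS-fed males, 54.9% to 80.7% in CAS-fed and 55.0% to 71.4% in AA-fed females, and batch 2 from 59.8% to 75.5% in AA-fed males. The male interaction went from 43.1% to 31.3% (batch 1), and the sex difference of AA on WD from 56.2% to 81.8% (batch 1), with 48.0% in batch 2. That of WD in AA-fed mice went from 42.6% to 100% and 23.1% in batches 1 and 2 and 53.0% with runs of 8. The held-out score of -0.305 moved to -0.408 with a set at an adjusted p under 0.01 and to -0.272 without the 4 arrays. The planned removal of arrays by interquartile range removed none. The mean of all probes of a gene and the camera and fry tests of gene lists were not run. Signal near background limits 18.0% of probes.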

Other observations

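The split of the sex-biased probes into male and female sets was a choice made after the data were seen, and the tests on these sets were chosen then too, with those of level-matched probes and of female RNA written down before their results were seen. The female-biased set held the 210 probes higher in females, and the male-biased set the 208 higher in males, by at least 1 on the log2 scale over all diets.

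On WD, CAS-fed males moved toward the female level in both sets. The mean level of the female-biased set rose from 7.19 ± 0.10 on CD to 7.74 ± 0.16 on WD (SD, n = 8), by 0.55, with 8 of 8 mice on WD above all mice on CD (exact permutation test, two-sided p = 1.6e-04, the smallest that 8 against 8 allows, adjusted p = 4.1e-04 over 8 tests). The male-biased set differed by -0.23, with 5 of 8 mice on WD below all mice on CD (exact permutation p = 0.0228, adjusted p = 0.0457). In AA-fed males the differences were 0.10 and 0.07 (exact permutation p = 0.277 and 0.396). Their female-biased level was already 7.45 ± 0.18 on CD and was 7.55 ± 0.18 on WD (SD, n = 8), so that the smaller response reflects a higher level on CD as well as a lower one on WD. The WD response differed between AA-fed and CAS-fed males by -0.45 in the female-biased set (permutation p = 4.2e-04, adjusted p = 0.00168) and by 0.30 in the male-biased set (permutation p = 0.0148, adjusted p = 0.0296). In females the male-biased set rose on WD by 0.31 with CAS and 0.37 with AA, with 8 of 8 mice on WD above all mice on CD in each (exact permutation p = 1.6e-04). The gap between the sexes in CAS-fed mice went from 2.43 on CD to 1.94 on WD for the female-biased set and from -2.16 to -1.62 for the male-biased set. In AA-fed mice it went from 2.16 to 2.12 and from -2.04 to -1.75, the latter with the rise in females.

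Compression of the intensity range could bring high and low probes together. In 1000 draws per set of probes matched in level and not called between the sexes, the highest mean shift was 0.0503 for the female-biased set and the lowest was -0.0865 for the male-biased set, and 0 draws reached the shift of either set. Other probes of the same level thus did not share these shifts. The draws cannot decide on compression, since the normalization read from the values already gives every array the same distribution. They were also matched in level only, not in how much a probe varies. RNA from female livers in the samples of males on WD might raise the female-biased set, but A_55_P1952512, the probe with the largest female excess, differed by 0.0079 between WD and CD in CAS-fed males (exact permutation p = 0.914, n = 8). A partial loss of sex-biased expression in CAS-fed males on WD is a hypothesis that these values leave open, and it was found and tested on the same arrays. It does not account for the rise of the male-biased set in females. The sets were chosen on all 64 arrays, and sets chosen on the AA-fed arrays gave a rise of 0.67 in CAS-fed males. Within the female-biased set, 90 probes were called higher and 21 lower on WD in CAS-fed males, and within the male-biased set 43 were called higher and 103 lower.

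On CD, AA-fed males scored 0.15 and 0.14 above CAS-fed males on the probes that respond to WD, in the direction of the WD response (held-out wash batches, exact permutation p = 0.171 and adjusted p = 0.274 each, 2 of 4 AA-fed mice above all CAS-fed mice in each). Females on CD scored 0.11 and 0.07 in the same direction on the probes that respond in females (exact permutation p = 0.0571 and 0.229, adjusted p = 0.152 and 0.305, with 3 and 2 of 4 AA-fed mice above all CAS-fed mice). On WD, where AA-fed males scored lower, the females differed by 0.06 and -0.01 (exact permutation p = 0.486 and 0.714, adjusted p = 0.555 and 0.714, with 0 of 4 AA-fed mice below all CAS-fed mice in each). The scores rested on 4051 and 6181 probes in males and on 109 and 1017 in females. The WD response of CAS-fed mice on them was 0.577 and 0.544 in males and 0.825 and 0.438 in females.

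The DarkCorner control, which averaged 4.18 over all arrays, read 5.75 on Female CD AA replicate 5.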
